A study of Mus musculus with 8 samples.

How the data were processed

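Liver RNA of 8 LDLR-knockout recipients, 4 given wild-type and 4 given TTP-knockout bone marrow, was hybridised to 1-colour Agilent mouse arrays, with 1 array per animal. Groups and replicate numbers were taken from the sample labels. Per the file headers, the deposited scanner output was made with Agilent Feature Extraction, version 10.7.3.1 per the submitters' processing notes, and the array was annotated on the mm9 build. The deposited intensity values per spot are, per the file headers, background-subtracted and detrended signals (gProcessedSignal), together with median spot and local background intensities and flags for signal well above background, saturation and outlier spots. These intensities are not normalised between arrays. The authors also deposited a table of log2 values for the same arrays. Its scaling is not given in the sources used here. Set against the scanner values it was on the log2 scale, centred on each probe's median over the 8 arrays, and ran in the same direction as log2 signal after quantile normalization, with slopes from 0.998 to 1.00 per array. Which steps the authors took to reach that scaling stays unknown. The medians of its columns were −0.006, 0.0002, 0.001 and 0.0005 for wild-type marrow replicates 1 to 4 and −0.002, 0.008, 0.003 and −0.010 for TTP-knockout marrow replicates 1 to 4.

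Each array held 62976 spots, of which 59305 were not controls. No spot was saturated, and 0.22% were flagged as outliers and set missing on that array. Log2 of the processed signal was taken relative to each array's 75th percentile over non-control spots, and spots of one probe were averaged. Probes were named through the accession in the scanner file, without its version, matched to RefSeq gene names of assembly GRCm38.p6, from which no coordinates were used. Of 55681 probes 28026 (50.3%) matched, standing for 21154 genes, and the others were treated as unnamed. A probe was kept if its signal was well above background on at least 4 of the 8 arrays, whatever the group. That left 29815 probes, and each gene was represented by its kept probe with the highest mean, giving 14358 named genes and 11083 unnamed probes. Of the 104 genes and probes chosen to be named, 14 had several kept probes, and none of these had probes of opposite sign.

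The 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. All differences are TTP-knockout minus wild-type marrow recipients. Gene lists for pathways, cell types and neighbouring tissues, fixed before the data were examined, were tested with limma's camera (preset correlation 0.01, lists of at least 5 measured members, features with a missing value left out) and also with an estimated correlation. Members of each list were counted both after adjustment over all genes and adjusted over the list alone. The lists share members. Per-array list means and single values were compared by exact two-sided permutation tests over all 70 arrangements, which cannot give a p below 0.0286. Named genes follow a rule fixed before the data were examined: Zfp36, its 2 relatives and Ldlr, then, since under 10 genes passed, the 10 named genes with the smallest unadjusted p given as values, and up to 4 members with the smallest p for each shifted list. The median log2 difference of all genes was −0.02.

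The scripts were tested on simulated data with the means and residual spread of the 25441 features in this comparison. Of genes changed 4-fold, 95.5% were recovered, against 53.7% of those changed 2-fold and 11.9% of those changed 1.5-fold. In that run 7 unchanged genes were called as well. In simulated data without changes 0 genes and 0 lists were called. These simulations draw genes independently, so they do not show how camera behaves with correlated genes.

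All 8 arrays lay on 1 slide with 1 scan, so slide and scan date could not act as batches between groups, but each group filled its own slide row. Alternatives fixed before the data were examined were normexp background correction with offset 50 followed by quantile normalization, quantile normalization alone, median centring, no filter, a filter requiring all 8 arrays, the mean of a gene's probes, every probe by itself, an intensity-dependent robust prior, array weights, a replicate block, the authors' log2 table, other thresholds, fry for the lists, and leaving out each array. The normexp alternative was planned on mean spot signal and was run on median spot signal, the column in the files used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.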

Results

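Liver RNA was profiled from 8 female LDL receptor-deficient (LDLR-knockout) mice, a strain used to study atherosclerosis. All were irradiated at 8 weeks of age and given bone marrow, either from wild-type donors (4 recipients) or from donors lacking tristetraprolin (TTP), the product of Zfp36 and a protein that binds AU-rich mRNAs and speeds their decay (4 recipients). After 4 weeks they received a Western diet for 12 weeks, and livers were taken at 24 weeks of age. Each liver was hybridised to its own 1-colour array, with 200 ng of RNA labelled per sample. The arrays carried 55681 non-control probes. Between 29563 and 31185 probes lay well above background in the 4 wild-type marrow recipients, and between 28213 and 30344 in the 4 TTP-knockout marrow recipients. The 75th percentile of signal was 568 to 669 units in the first group and 450 to 716 in the second, with TTP-knockout marrow replicate 2 lowest on both measures. Correlations between arrays of log2 signal over genes were 0.9893 to 0.9933 within the wild-type marrow group, 0.9856 to 0.9895 within the TTP-knockout marrow group and 0.9816 to 0.9909 between groups. The labels call the 4 samples of a group biological replicates, and it is their number that limits the precision of every value given here.

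The comparison asks how liver expression in LDLR-knockout mice differs when the transplanted marrow lacks TTP. Zfp36 itself was measured first. Its level was −0.15 ± 0.22 in the TTP-knockout marrow recipients and −0.21 ± 0.46 in the wild-type marrow recipients (mean ± SD of log2 signal relative to the array's 75th percentile, n = 4 each), a difference of 0.06 ± 0.23 (SE, adjusted p = 0.916 in limma). This does not check the labels, since only donor cells lack TTP, host liver cells keep Zfp36, and the probe may lie outside the deleted part of the gene. Its relatives Zfp36l1 (−0.02 ± 0.15 SE, adjusted p = 0.957; slightly positive under quantile, normexp and the authors' scaling) and Zfp36l2 (0.36 ± 0.15 SE, adjusted p = 0.286) did not pass either. Nor did Ldlr, disrupted in every host (0.25 ± 0.17 SE, adjusted p = 0.482). Its probe was well above background on all 8 arrays, with means of −0.09 in the TTP-knockout and −0.34 in the wild-type marrow recipients. This does not check the host genotype either, since the probe may lie outside the disrupted part and donor cells are not labelled as lacking Ldlr.

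Of 25441 genes and unnamed probes tested, 5 rose in the TTP-knockout marrow recipients at an adjusted p under 0.05 in limma, and none fell. The largest rises were in Y-linked Ddx3y and Eif2s3y, a helicase and a translation factor subunit. Both were well above background on all 4 TTP-knockout marrow arrays and on 0 of the 4 wild-type marrow arrays. Ddx3y was at least 10.6-fold higher (adjusted p = 3.5e-05) and Eif2s3y at least 13.2-fold higher (adjusted p = 5.4e-05), where the bound sets the bright group's mean against the lowest signal counted as well above background on each dim array, or the probe's own if higher. These bounds hold for the main processing only. With normexp the log2 differences were smaller, 2.195 for Ddx3y and 2.385 for Eif2s3y. Xist, the transcript of the inactive X chromosome in female cells, was well above background on all 8 arrays, and its brightest probe differed by 0.27 on the log2 scale (exact permutation p = 0.257, two-sided). All hosts are labelled female, and donor sex is not stated in the labels. Donor genotype therefore differed together with Y-linked signal in all 8 livers, which holds for every difference described below.

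**Figure D1:**
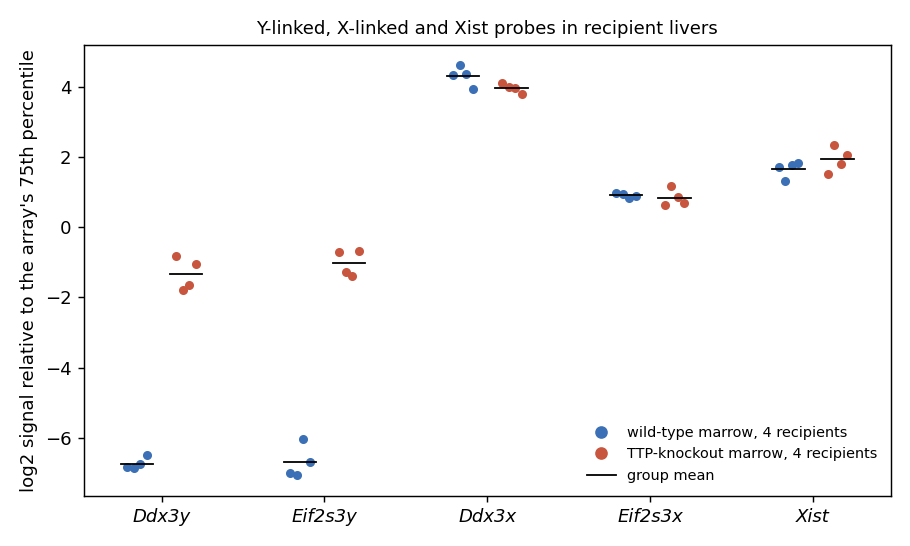
Log2 signal relative to each array's 75th percentile (vertical axis) for the brightest probe of 5 sex-linked genes in the 4 wild-type marrow recipients (blue) and the 4 TTP-knockout marrow recipients (red), with group means as lines. Ddx3y averaged −6.74 in the first group and −1.33 in the second, whereas Xist averaged 1.67 and 1.94.

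Neurotrophin 3 (Ntf3), a nerve growth factor family member, was 4.51-fold higher in the TTP-knockout marrow recipients (log2 difference 2.17 ± 0.15 SE, adjusted p = 0.00124). Spink1, a secreted trypsin inhibitor, was 3.38-fold higher (1.76 ± 0.15 SE, adjusted p = 0.00495). The Spink1 call ended with a block for replicate number (adjusted p = 0.149). The probe A_55_P2034655, which has no gene name here, was 3.62-fold higher (1.86 ± 0.19 SE, adjusted p = 0.0259). Its call ended without wild-type marrow replicate 1, 3 or 4 or TTP-knockout marrow replicate 1 or 3, with adjusted p from 0.0556 to 0.139. It also ended without the filter on dim probes (0.105) and with the block (0.149). In all 5 the 4 values of one group lay above the 4 of the other. The other genes with the smallest unadjusted p had adjusted p between 0.0502 and 0.0547, so their values are given without a call. Log2 differences were 1.47 for the acute phase protein gene Saa2, 1.02 for Fgl1, a hepatocyte-secreted fibrinogen-like protein, and 0.86 for Jaml, a leukocyte adhesion molecule. They were −1.08 for Abcg5, which encodes part of the sterol exporter, −2.25 for the connexin gene Gjb3 and −2.25 for the peroxisomal oxidase gene Hao2. Hao2 was well above background on none of the TTP-knockout marrow arrays (at least 1.90-fold lower), and Gjb3 on 2 of 4. With normexp the log2 differences were smaller, −0.68 for Hao2 and −1.05 for Gjb3, so the bound for Hao2 holds for the main processing only. At an unadjusted p under 0.05, 1829 were higher and 2172 lower, 4001 against 1272 by chance, and in 2545 the 2 groups did not overlap, against 727 by chance. These chance counts are averages without a spread. Over the other splits of the 8 arrays into 4 and 4 the first count ranged from 299 to 3438. The count without overlap was not taken over other splits. The count of 5 depended on the setting, being 157 (70 higher, 87 lower) with an intensity-dependent robust prior, 65 with array weights, 46 (26 higher, 20 lower) with normexp, 17 without TTP-knockout marrow replicate 2 and 8 without replicate 4. The wild-type marrow arrays filled 1 row of the slide and the TTP-knockout marrow arrays the other, so slide row and group cannot be told apart.

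**Figure D2:**
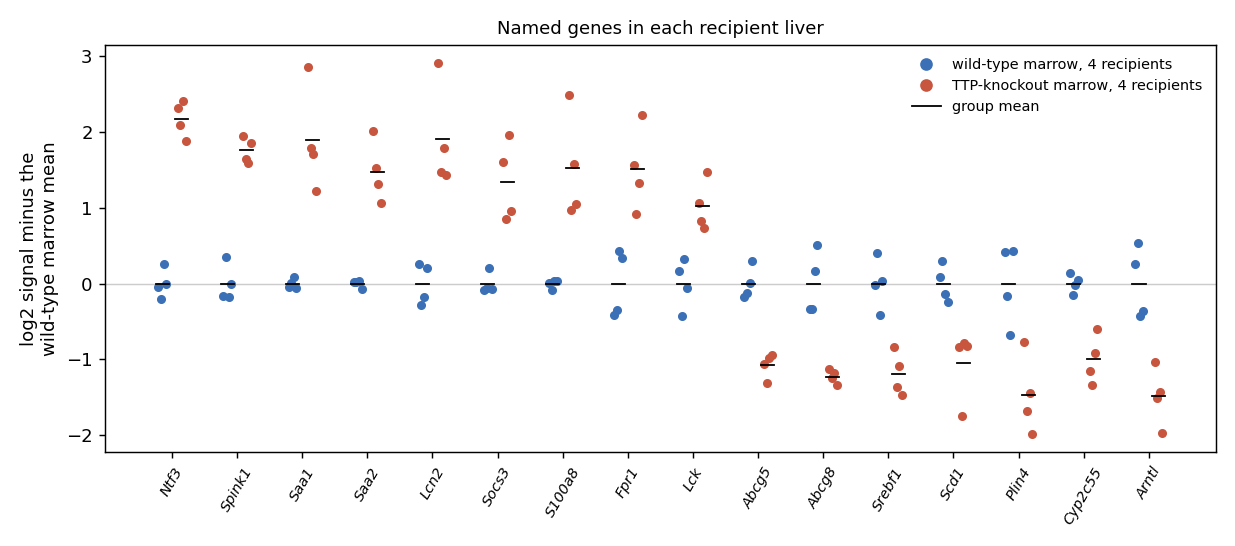
Log2 signal of 16 named genes in each recipient liver, minus that gene's mean in the wild-type marrow group (vertical axis), with blue points for the 4 wild-type marrow recipients, red points for the 4 TTP-knockout marrow recipients and lines for group means. Ntf3 and Spink1 passed the adjusted threshold, and the other genes shown did not, although the groups did not overlap for any of them.

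Gene lists fixed before the data were examined were compared with all other genes by limma's camera with a preset correlation of 0.01. Of 35 lists, 12 were shifted up and 11 down in the TTP-knockout marrow recipients. No list member passed the threshold adjusted over all genes, so members are given as values. With an estimated correlation, 1 list, xenobiotic metabolism, kept its call (adjusted p = 0.0429), and 5 of the 35 splits of the 8 arrays, the real split included, gave at least 23 shifted lists. For 11 of the shifted lists the per-array mean of the members did not overlap between the groups (1 by chance), each with an exact permutation p of 0.0286, the smallest that 4 against 4 can give. None of these passed Benjamini-Hochberg adjustment (adjusted p = 0.0909 for each). That value is set by the smallest possible p and by 11 of 35 lists reaching it, whatever the size of the differences.

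The neutrophil and granulocyte markers had the largest median difference, 1.26 on the log2 scale, and rose as a list (adjusted p = 6.1e-09, adjusted p = 0.242 with an estimated correlation). All 20 measured members were higher, 8 of them past the threshold adjusted over the list alone. Differences were 1.14 for Retnlg, 1.52 for the calcium-binding protein gene S100a8 and 1.51 for the formyl peptide receptor gene Fpr1. The collagenase gene Mmp8 had a measured difference of 1.62 but was well above background on 3 of 4 TTP-knockout and 1 of 4 wild-type marrow arrays. TTP-knockout marrow replicate 1 stood apart on this list, with a mean of 1.86 against 0.02 to 0.25 on the other TTP-knockout marrow arrays, and without it the median difference was 0.76 (adjusted p = 3.8e-07). The T and NK cell list rose too (median 0.75, adjusted p = 1.6e-07, adjusted p = 0.278 with an estimated correlation), with 18 of 20 members higher and 5 past the threshold adjusted over the list alone. Thy1 differed by 0.66, the T cell kinase genes Lck and Itk by 1.02 and 0.90, and Cd2 by 0.80. B and plasma cell markers rose by a median of 0.47 (13 of 14 higher, 0 past the threshold adjusted over the list alone, adjusted p = 2.2e-05, adjusted p = 0.280 with an estimated correlation), including Pou2af1 at 1.04 and Jchain at 1.44. The 2 groups overlapped on the last 2 lists. With normexp the medians of the neutrophil, T and NK cell and B and plasma cell lists were 0.77, 0.49 and 0.26.

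Acute phase genes rose as a list (median 0.35, adjusted p = 2.3e-07, adjusted p = 0.254 with an estimated correlation). Of 33 measured members 26 were higher, 12 past the threshold adjusted over the list alone. Saa1, encoding serum amyloid A, was higher by 1.89 ± 0.29 (SE), the siderophore-binding lipocalin gene Lcn2 by 1.90 ± 0.31 and the cytokine-induced inhibitor gene Socs3 by 1.34 ± 0.24. The interferon gamma list rose (median 0.55, 22 of 22 higher, 2 past the threshold adjusted over the list alone, adjusted p = 3.9e-07, adjusted p = 0.441 with an estimated correlation), with Nlrc5, a regulator of MHC class I genes, at 0.73 and the immunoproteasome gene Psmb9 at 0.89. Its mean was 1.41 on TTP-knockout marrow replicate 1 against −0.27 to 0.33 on the other TTP-knockout marrow arrays, and without replicate 1 its median was 0.25 (adjusted p = 0.00093). On the wild-type marrow arrays its mean was −0.53 to 0.09, so the groups overlapped (exact permutation p = 0.114). The type I interferon list rose by a median of 0.30 (22 of 26 higher, adjusted p = 9.0e-05, adjusted p = 0.453 with an estimated correlation), with the antiviral enzyme genes Oas1a at 0.54 and Oas2 at 0.73, and its call ended without the filter on dim probes (adjusted p = 0.0594). Here too the groups overlapped (exact permutation p = 0.2), with means of −0.19 on TTP-knockout marrow replicate 3 and 0.03 on wild-type marrow replicate 3. MHC class II genes (median 0.50, 10 of 11 higher, adjusted p = 0.00205), inflammasome genes (0.31, 13 of 16 higher, adjusted p = 0.00437), NADPH oxidase subunits (0.29, 9 of 10 higher, adjusted p = 0.0285) and bile duct markers (0.35, 9 of 11 higher, adjusted p = 0.0222) rose with 0 members past the threshold adjusted over the list alone. With an estimated correlation their adjusted p values were 0.450, 0.441, 0.303 and 0.330, and all 4 calls ended without TTP-knockout marrow replicate 1 (adjusted p = 0.0798, 0.0536, 0.0511 and 0.0680). The NADPH oxidase call also ended without wild-type marrow replicate 1 or 2 (adjusted p = 0.178 and 0.0531) or TTP-knockout marrow replicate 4 (0.0931), and that of bile duct markers without wild-type marrow replicate 1 (0.202) or TTP-knockout marrow replicate 3 (0.115). Without the filter on dim probes the inflammasome, NADPH oxidase and bile duct calls ended too (adjusted p = 0.222, 0.327 and 0.344). On the MHC class II, inflammasome and bile duct lists the groups overlapped (exact permutation p = 0.229, 0.143 and 0.171). Without TTP-knockout marrow replicate 1 the MHC class II median was 0.17, and without replicate 4 the NADPH oxidase median was 0.15 (0.148). The NADPH oxidase median was also 0.14 with normexp and 0.19 with every probe taken by itself, and the bile duct median was 0.18 (0.175) with normexp. Members of these lists included Ciita at 0.89, the DNA sensor gene Aim2 at 0.57, the phagocyte oxidase genes Ncf1 at 0.78 and Ncf4 at 0.74, and Cdh1 at 0.70.

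The list of inflammatory cytokines and adhesion molecules was at the edge (adjusted p = 0.0434, adjusted p = 0.699 with an estimated correlation), with 15 of 28 members higher, a median of 0.02 and 5 members higher past the threshold adjusted over the list alone. Differences were 1.36 for Ccr5, 0.92 for Cd14 and 2.75 for Ccl8. Its median was −0.004 with normexp and ranged from −0.07 to 0.20 with 1 array left out, lowest without TTP-knockout marrow replicate 1 and highest without replicate 2. Without TTP-knockout marrow replicate 1 its adjusted p was 0.745, and the call also ended without TTP-knockout marrow replicate 3 or 4 or wild-type marrow replicate 1 or 4 (adjusted p from 0.104 to 0.147), without the filter on dim probes (0.892) or with every probe taken by itself (0.0592). Known TTP target mRNAs were not shifted (adjusted p = 0.151): 17 of 23 were lower, the median was −0.30, and 0 passed the threshold adjusted over the list alone. Their mean was −1.07 on TTP-knockout marrow replicate 2 against −0.09 to 0.59 on the other TTP-knockout marrow arrays. On the wild-type marrow arrays it was −0.31 to 0.51.

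Genes of oxidative phosphorylation fell together. All 40 measured members were lower (median log2 difference −0.31, and −0.20 with quantile normalization, with normexp and in the authors' table), and 21 passed the threshold adjusted over the list alone (list adjusted p = 1.3e-16, adjusted p = 0.242 with an estimated correlation). Cyc1, a complex III subunit, differed by −0.57, the succinate dehydrogenase genes Sdha and Sdhb by −0.48 and −0.49, and Uqcrc2 by −0.42. Xenobiotic metabolism genes fell (median −0.38, 20 of 23 lower, adjusted p = 1.1e-07), with 9 past the threshold adjusted over the list alone. The glutathione transferase gene Gstt1 differed by −0.78 ± 0.11 (SE) and the cytochrome P450 genes Cyp2c55, Cyp1a2 and Cyp2c29 by −0.999, −0.72 and −0.70.

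Lipid genes were lower in several lists. Lipid droplet and PPAR gamma genes fell (median −0.44, 18 of 20 lower, 4 past the threshold adjusted over the list alone, adjusted p = 2.2e-06, adjusted p = 0.242 with an estimated correlation), including the droplet coat gene Plin4 at −1.47, Fitm1 at −1.35, Fabp4 at −0.66 and the fatty acid transporter gene Cd36 at −0.55. Plin4 and Fabp4 are also adipocyte genes, and the adipose and pancreas list fell as well (median −0.43, with Cfd at −2.55), likewise without overlap between the groups. That call ended with an estimated correlation (adjusted p = 0.242) and without the filter on dim probes (adjusted p = 0.222, median 0.09). It rested on 5 measured genes of 16 listed, from both tissues. Cfd was 6.4 on wild-type marrow replicate 4 against 2.7 to 3.6 on the other wild-type marrow arrays. Fatty acid and triglyceride synthesis genes fell (median −0.26, 22 of 26 lower, 8 past the threshold adjusted over the list alone, adjusted p = 3.6e-05, adjusted p = 0.242 with an estimated correlation). The lipogenic regulator gene Srebf1 differed by −1.19 ± 0.20 (SE), the desaturase genes Scd1 and Fads2 by −1.04 and −0.84, and Dgat1 by −0.49. Lipoprotein genes fell (median −0.14, 23 of 30 lower, 3 past the threshold adjusted over the list alone, adjusted p = 0.00184, adjusted p = 0.242 with an estimated correlation), with Abcg8 at −1.23, Angptl3 at −0.57 and Abca1 at −0.46. Fatty acid oxidation genes fell (median −0.25, 27 of 30 lower, 1 past the threshold adjusted over the list alone, adjusted p = 1.4e-04, adjusted p = 0.450 with an estimated correlation), with Acaa1b at −0.67 and Acot1 at −0.75. On this list the groups overlapped (exact permutation p = 0.0857). Bile acid genes fell (median −0.22, 18 of 22 lower, adjusted p = 0.00495, adjusted p = 0.242 with an estimated correlation), with the transporter gene Slco1a4 at −0.68 and the hydroxylase gene Cyp7b1 at −0.87. The lipoprotein and bile acid calls ended under quantile normalization (adjusted p = 0.0502 and 0.121) and in the authors' table (0.0837 and 0.129), and the bile acid call also with normexp (0.117). Under quantile normalization, with normexp and in the authors' table the bile acid median was −0.11, −0.12 and −0.13, that of fatty acid oxidation was −0.16, −0.12 and −0.16, and that of the lipoprotein list was −0.09 in the authors' table. Without TTP-knockout marrow replicate 1 the medians of the lipoprotein, fatty acid oxidation and bile acid lists were −0.09, −0.16 and −0.15 (−0.145), and without replicate 2 that of the lipoprotein list was −0.22.

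Among the remaining shifted lists, oxidative stress and NRF2 targets fell (median −0.23, 21 of 26 lower, adjusted p = 5.0e-04, adjusted p = 0.242 with an estimated correlation), with the peroxide-reducing enzyme genes Gpx4 and Prdx3 both at −0.35. That call ended under quantile normalization (adjusted p = 0.115) and in the authors' table (0.124), where the median was −0.13 in each, and with normexp it was −0.12. Male-biased liver genes fell (median −0.33, 11 of 16 lower, adjusted p = 0.00561, adjusted p = 0.467 with an estimated correlation), with Igf1 at −0.40 and Elovl3 at −1.71, and the call ended without wild-type marrow replicate 2 (adjusted p = 0.0609), under quantile normalization (0.0502) and in the authors' table (0.0730). Per-array means of this list overlapped (exact permutation p = 0.143). They were −0.11 and −0.13 on wild-type marrow replicates 1 and 3, below 0.14 on TTP-knockout marrow replicate 2. Clock genes were shifted up (median 0.24, 13 of 18 higher, adjusted p = 0.0404, adjusted p = 0.330 with an estimated correlation), but individual genes went both ways: Per3 and Dbp differed by 1.24 and 1.33, and Arntl, which encodes the BMAL1 transcription factor, by −1.48. The call ended without wild-type marrow replicate 1 (adjusted p = 0.0981) or TTP-knockout marrow replicate 3 (0.157), and without the filter on dim probes (0.892). Per-array means of the clock list overlapped as well (exact permutation p = 0.143).

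Markers of cell types and neighbouring tissues moved by different amounts. Hepatocyte identity genes fell (median −0.17, 17 of 20 lower, adjusted p = 0.00437, adjusted p = 0.467 with an estimated correlation), including the amino acid enzyme genes Pah at −0.49 and Hpd at −0.44. Without TTP-knockout marrow replicate 2 or 4 that median was −0.27 or −0.11, and in the authors' table it was −0.11. The groups overlapped on this list (exact permutation p = 0.0857). Adipose and pancreas markers fell (median −0.43, 4 of 5 lower, adjusted p = 0.0203, adjusted p = 0.242 with an estimated correlation), with the adipocyte gene Cfd at −2.55. Without the filter on dim probes all 16 listed members entered, their median was 0.09 against 0.13 for all features, and the call ended (adjusted p = 0.222). Their mean was highest on wild-type marrow replicate 4, at 0.97 against 0.06 to 0.32 on the other wild-type marrow arrays. Markers of sinusoidal endothelium (median −0.14, adjusted p = 0.0888), Kupffer cells (0.06, adjusted p = 0.891), stellate cells and fibrosis (0.09, adjusted p = 0.339), erythroid cells (0.03, adjusted p = 0.590) and monocytes and recruited macrophages (−0.11, adjusted p = 0.608) were not shifted. In the last list 3 members were higher and 3 lower past the threshold adjusted over the list alone. The lists of cell cycle (0.10, adjusted p = 0.0646), cholesterol synthesis (−0.06, adjusted p = 0.912), unfolded protein and integrated stress response (0.09, adjusted p = 0.862), glucose production and insulin response (−0.07, adjusted p = 0.270), immediate early genes (−0.08, adjusted p = 0.187) and female-biased liver genes (−0.09, adjusted p = 0.187) were not shifted either, with their median log2 differences given first.

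**Figure D3:**
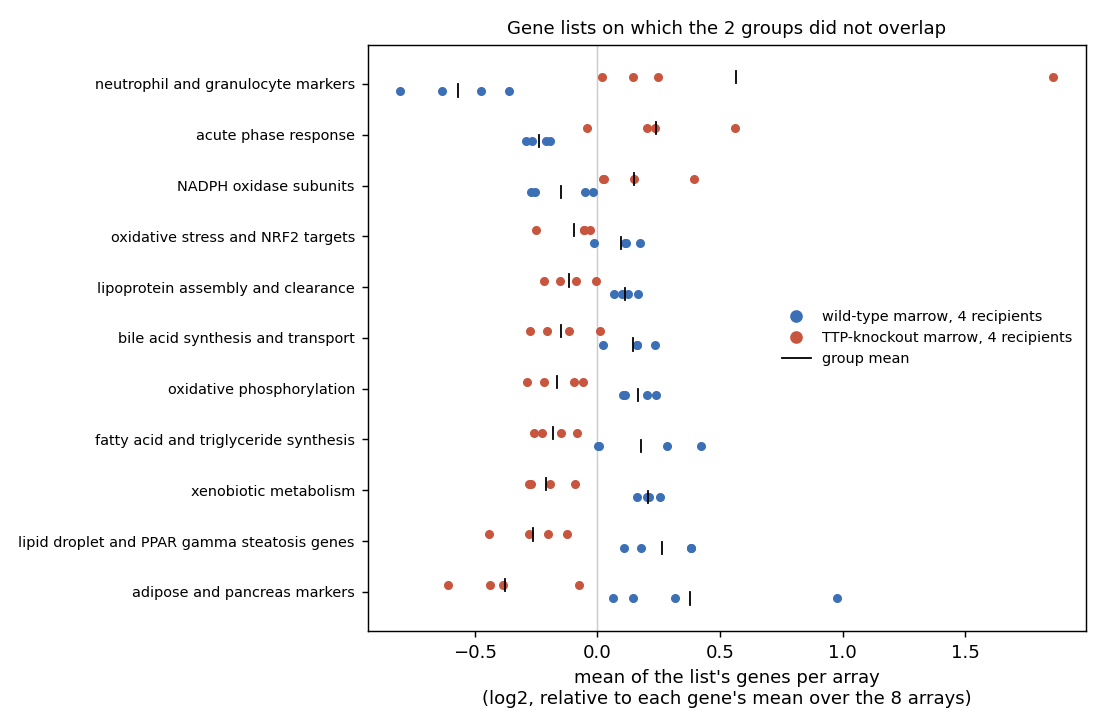
Mean of each list's measured genes on each array (horizontal axis, log2, relative to each gene's mean over the 8 arrays) for the 11 lists whose groups did not overlap, with blue points for the 4 wild-type marrow recipients, red points for the 4 TTP-knockout marrow recipients and lines for group means. Neutrophil, acute phase and NADPH oxidase genes lay higher in the TTP-knockout marrow recipients and the other 8 lists lay lower.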

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

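The tests of explanations in this part were chosen after the results they bear on were seen; of the counts over other splits of the samples, those of genes and of shifted lists were prescribed but were read before their bounds were written down, and that of lists without overlap was added after seeing the data.

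In 14 of 286 checked groups of 4 values, 1 array stood apart from the other 3 by more than Dixon's 95% limit, and chance alone gives about 14.3. By this measure, the mean of the neutrophil list was 1.86 on TTP-knockout marrow replicate 1, and that of the NRF2 targets −0.25 on replicate 2. TTP-knockout marrow replicate 1 also had Acaa1b at 6.54 and Per3 at −2.21 (−2.205), replicate 2 had Scd1 at 6.36 and Elovl3 at 0.78, and replicate 4 had the probe A_55_P2034655 at 2.18 and Cdh1 at −0.24. Wild-type marrow replicate 1 had Acaa1b at 7.40 and Prdx3 at 3.67, replicate 3 had Ccl8 at −1.30, Socs3 at 1.71 and Sctr at −3.24, and replicate 4 had Saa2 at 7.51 (all log2).

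Y-linked Ddx3y and Eif2s3y were both well above background on 4 of the 4 TTP-knockout marrow arrays. Male hosts in that group are argued against by Xist, which differed by 0.27 ± 0.20 (SE) where a fall of more than 1 was needed. Probes reading the X-linked relatives are argued against too: Ddx3x and Eif2s3x were bright on all arrays, the larger difference was −0.35, and the Y-linked probes stayed dim in the wild-type marrow recipients. Male donor cells in female hosts, in the TTP-knockout marrow group alone, stay open as a candidate explanation that these arrays do not settle: of the 6 other Y-linked genes on the array, any was well above background on 1 TTP-knockout and 0 wild-type marrow arrays, and probes this dim decide nothing. The gene counted there was Uty. Its probe read −3.49, −5.84, −6.16 and −4.36 on TTP-knockout marrow replicates 1 to 4, and −6.73 to −6.39 on the wild-type marrow arrays.

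The 3 leukocyte lists (neutrophils, T and NK cells, B and plasma cells) were higher while 8 metabolic lists were lower in the TTP-knockout marrow recipients, calls that with an estimated correlation held only for xenobiotic metabolism (adjusted p from 0.242 to 0.280 for the leukocyte lists). A smaller share of hepatocytes in the RNA would raise other cell types alike, and the leukocyte mean exceeded that of endothelial, Kupffer, stellate and bile duct lists by 0.72 with overlap (exact permutation p = 0.0857), although without TTP-knockout marrow replicate 3 (0.92) the groups were apart; the neutrophil list alone exceeded them by 1.06 with overlap, 0.58 without TTP-knockout marrow replicate 1, and was apart when the bile duct list was left out (1.12). The metabolic lists differed from hepatocyte identity by a further −0.14 with overlap (exact permutation p = 0.143), −0.09 without TTP-knockout marrow replicate 2 and −0.18, then apart, without wild-type marrow replicate 1, so a change in cell shares cannot be told apart from a change within cells. More blood of the same make-up left in the tissue is argued against by erythroid markers, which the leukocyte means exceeded by 0.82 without overlap. The erythroid mean itself differed by −0.03. Of 9 measured erythroid members 5 were higher and 4 lower, 2 of the latter past the threshold adjusted over the list alone. These markers do not measure the leukocyte content of blood, so blood richer in leukocytes stays open. Donor sex in place of donor genotype cannot be told apart, since 0 of the wild-type marrow arrays had both Y-linked genes above background, and loss of TTP in donor cells stays open beside it.

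Gpnmb and Trem2, genes of lipid-laden macrophages chosen after their values were seen, differed by −2.81 and −1.33 (adjusted p = 0.0703 and 0.0748 in limma). Relative to the Kupffer cell list the mean of the pair differed by −2.14 without overlap. The pair was chosen after its values were seen, so that lack of overlap is no separate evidence. The mean of the Kupffer cell list itself differed by 0.07, against −2.07 for the pair. This argues against an equal fall in macrophages of every kind. Other macrophage genes went both ways without passing the threshold over all genes, with Csf1r at 0.63, Ctsd at −0.36, Cd68 at −0.59 and Mmp12, above background on 2 TTP-knockout marrow arrays, at −1.33 (adjusted p = 0.241, 0.192, 0.261 and 0.317), so fewer macrophages of some kinds stay open. Without TTP-knockout marrow replicate 2, the dimmest array, the mean difference of the pair was −1.75, so it did not rest on that array alone. The groups still did not overlap, but leaving out an array cannot make separate groups overlap, so this decides nothing. Donor sex and genotype both remain open, untested.

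Over the 35 splits of the 8 arrays into 4 and 4, 1 split, the real one, gave as many as 5 genes. The highest other count was 1, which argues against chance for the count of 5. It cannot exclude chance, since 1 in 35 is the smallest share these splits can give. Y-linked Ddx3y and Eif2s3y are among the 5. At an unadjusted p under 0.05, 1 split reached 4001, with 3438 as the highest other. For the 23 shifted lists, 5 splits gave as many and the highest other gave 27, so chance cannot be excluded for the number of lists. For the 11 lists without overlap, 1 split gave as many and the highest other gave 4, which argues against chance for that count, although the criterion was chosen after seeing the data.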

How the results depend on the processing

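The count of 5 genes (5 higher, 0 lower) was 46 (26 and 20) with normexp, 10 (8 and 2) with quantile normalization, 7 (5 and 2) with median centring and 7 (6 and 1) in the authors' table. It was 17 with probes well above background on all 8 arrays, 157 (70 and 87) with the intensity-dependent robust prior and 65 (42 and 23) with array weights. At an adjusted p under 0.1 it was 162 (91 and 71), and at an unadjusted p under 0.05 with at least 1.5-fold it was 1352 (945 and 407). Leaving out 1 array gave 4 to 17, highest without TTP-knockout marrow replicate 2. The cause was not tested. With the replicate block 3 genes passed, Spink1 and A_55_P2034655 being lost (adjusted p = 0.149 for both). The labels do not say that the shared numbers pair mice, but same-numbered arrays shared a slide column. Deviations of same-numbered arrays correlated at −0.105 to 0.203, and 2 of 4 arrays correlated best with their own number. These 4 correlations cannot decide whether the numbers pair the samples. The 23 lists became 1 with an estimated correlation, 7 (all lower) with fry, and 11 (3 higher, 8 lower) by per-array means without overlap, a criterion chosen after seeing the data. Leaving out 1 array gave 19 to 27 lists, and the block 21, without the cytokine and clock lists (adjusted p = 0.0522 and 0.0817). Without the filter 22 lists were shifted (6 higher, 16 lower), 16 of them shared with the 23, and the median log2 difference of all features was 0.13. Of the calls of single lists, 19 were lost and 234 kept over the processing alternatives, and 17 were lost and 167 kept over the left-out arrays. Zfp36 was −0.0313 with array weights and −0.15 to 0.22 with 1 array left out. Zfp36l1 was 0.0290 with normexp, 0.0621 with quantile normalization and 0.0640 in the authors' table, and −0.11 to 0.10 with 1 array left out, so neither has a direction. Among other named genes no direction reversed, and 64 calls were gained and 3 lost over the processing alternatives, namely the 2 under the block and A_55_P2034655 without the filter. Signal over background limits Hao2, Gjb3, Mmp8, Cxcl13, Ces1a and the Y-linked genes, whose folds are bounds or whose differences rest on some arrays of a group.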

Other observations

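Genes in this part were chosen after their values were seen, and the tests of the clock and of LXR targets against hepatocyte identity were chosen after the results; the first LXR test was fixed before its genes were read.

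Outside the lists, several further genes had adjusted p between 0.05 and 0.1 in limma with no overlap between the groups, and their values describe these livers only. The B cell chemoattractant gene Cxcl13 was higher in the TTP-knockout marrow recipients by 3.39 ± 0.64 (log2, SE; well above background on 4 TTP-knockout and 3 wild-type marrow arrays), the lectin receptor gene Clec10a by 1.37 ± 0.19, the short-chain fatty acid receptor gene Ffar2 by 1.12 ± 0.19 and Cd101 by 0.96 ± 0.16. The trefoil factor gene Tff3 was higher by 1.44 ± 0.25 and Pi16 by 1.34 ± 0.18. The growth hormone receptor gene Ghr differed by −0.55 ± 0.10, Car3 by −1.38 ± 0.26, the citrate and succinate transporter gene Slc13a2 by −1.70 ± 0.28 and the stress-induced growth factor gene Gdf15 by −1.04 ± 0.20 (−1.035). Inside the monocyte and recruited macrophage list, which was not shifted, Ccr2 differed by 1.46 ± 0.46, Plac8 by 1.16 ± 0.34 and Cd68 by −0.59 ± 0.23. Their adjusted p values were 0.206, 0.187 and 0.261, and the groups overlapped for Ccr2 and Cd68.

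Of 12 measured carboxylesterase genes of the Ces1 and Ces2 families, 11 were lower, led by Ces2b at −1.47, Ces1e at −0.87 and Ces2c at −0.80, with Ces1a, well above background on 3 TTP-knockout and 4 wild-type marrow arrays, at 0.33 as the exception; 11 were lower under quantile, normexp and the authors' scaling as well. Their mean per array differed by −0.59, a value made from the genes that drew attention.

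Abcg5, Abcg8, Srebf1, Scd1 and Abca1, all targets of the sterol-sensing receptor LXR, were lower, and a candidate explanation is lower LXR activity. In 8 LXR targets outside the lists 7 were lower, and their mean differed by −0.18 without overlap (exact permutation p = 0.0286, the smallest possible). Single differences were small. The smallest unadjusted p among the 8 in limma was 0.065, for Abcg1 at −0.40, and the 1 higher gene was Nr1h3 at 0.08. The hepatocyte identity list also differed by −0.18, the difference between the 2 being 0.0033 with overlap (exact permutation p = 0.943) and −0.07 to 0.12 with 1 array left out, lowest without TTP-knockout marrow replicate 4 and highest without replicate 2, so LXR activity and a shift of hepatocyte genes in general cannot be told apart at this spread.

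Per3, Dbp and Arntl, which differed in opposite directions, raised the question whether the groups stood at different clock phases. Among the remaining genes, 9 of 9 in phase with Dbp were higher and 3 of 3 in phase with Arntl lower, the contrast being 1.16 on the log2 scale, but the groups overlapped (exact permutation p = 0.0571). Bhlhe41 and Cry1, which are among them, were well above background on some arrays of a group only. A difference in phase, which could come from the time of collection, a time the labels do not give, or from the marrow, therefore stays open.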
